A study of Mus musculus with 3 samples.

How the data were processed

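Gene expression was measured in 3 populations of mouse cells sorted by the brightness of green fluorescent protein (GFP). The cells were Hb9-GFP embryonic stem cells, in which GFP reports on Hb9, the motor neuron transcription factor encoded by Mnx1. Per the labels, the stem cells were grown on feeder cells and differentiated toward motor neurons as embryoid bodies with retinoic acid and purmorphamine, a small-molecule agonist of the Hedgehog pathway. The sorted populations were GFP high, GFP low and GFP negative, with 1 array each. Groups were taken from the sample labels. Total RNA was amplified to biotin-labelled cRNA, per the labels' protocols, and the probe names are those of an Illumina bead array with 25697 probes.

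The authors deposited a linear signal intensity per probe and array without normalization, per the file headers. Its lowest values were 76.7, 77.7 and 79.4 on the GFP high, low and negative arrays, so background had not been subtracted. Beside each intensity the authors deposited a detection p-value, per the file headers, which compares the probe with control probes of the same array. Those control probes were not used here. The detection p-values step by 1 in 798. GenomeStudio was named per the submitters' processing notes, with its version not given in the sources used here. The authors also deposited a value table of linear intensity with a floor of 10, which held 47.5% of the probes on each array. Its background subtraction and its normalization between arrays are not given in the sources used here. Its medians were 12.6 on the GFP high array, 12.5 on the GFP low array and 12.5 on the GFP negative array. Over 5310 probes with a signal above 300 on all arrays, its differences from the mean of the arrays correlated with those of the non-normalized intensities at 0.994, 0.991 and 0.994 for the GFP high, low and negative arrays. That comparison tied each of its columns to an array and settled its scale and direction.

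The non-normalized intensities were background-corrected with normexp, with background parameters estimated from the detection p-values, given an offset of 16, quantile normalized and put on a log2 scale with limma 3.58.1 in R 4.3.3. The offset draws the folds of dim genes toward 1, so their folds are understated. The estimated background had a mean of 93.4, 96.1 and 95.4 and an SD of 5.95, 6.54 and 5.96 on the GFP high, low and negative arrays. Further steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Gene names came from the platform annotation, in which 23978 probes have 1 symbol, 0 have several and 1719 have none listed. Of these symbols, 23962 were matched through their gene ID to a current gene table and 0 differed from it. Each of the 16593 genes was represented by its brightest probe by mean over the 3 arrays, and 4777 genes had more than 1 probe. A gene was called detected at a detection p-value under 0.01. For 8 genes the brightest probe was not detected on any array while another probe was. No genome build is given in the sources used here, so no coordinates are printed.

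With 1 array per group there was no replicate check, no test and no p-value for any difference, and the number of arrays limits the precision. Differences of normalized log2 signal were counted at a size of at least 2-fold among genes detected on at least 1 of the 2 arrays compared. Where a gene was not detected on the dimmer array, the fold is a lower bound, written as at least N-fold. It sets the brighter signal against the higher of the dim probe's own signal and the lowest normalized signal of any detected probe on that array, which was 5.13, 5.13 and 5.14 on the log2 scale for GFP high, low and negative. As a gauge of technical spread, the brightest and second probes were compared in 2370 genes with at least 2 detected probes. From the departures between them, the SD of a single probe's log2 difference was 0.33 for GFP high against negative, 0.26 for GFP high against low and 0.29 for GFP low against negative. This covers probe choice. It does not cover what all probes of 1 array share, such as RNA amplification and hybridisation, or differences between cultures or sorts.

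The comparisons, the settings, their alternatives, 25 gene lists and the rule for named genes were chosen before the data were examined. The lists held motor neuron transcription factors, cholinergic and motor neuron effector genes, cranial motor neuron genes, pan-neuronal and axonal cytoskeleton genes, synaptic vesicle and release genes, axon guidance and adhesion genes, voltage-gated channel genes, neural progenitor genes, Sonic hedgehog pathway and floor plate genes, Notch pathway genes, cell cycle genes, pluripotency genes, spinal interneuron transcription factors, other neurotransmitter genes, glial genes, fibroblast, feeder and mesenchyme genes, endoderm and epithelial genes, endothelial genes, anterior and posterior Hox genes, retinoic acid response genes, immediate early and stress genes, motor neuron disease genes, glycolysis genes and reference genes. Together they had 366 entries, of which 49 had no named probe here, and 315 different genes could be measured. For each list the median log2 difference of its detected members was set against 10000 random lists of the same size, matched on mean signal in 20 bins. The resulting percentile describes these arrays and is not a test. The named genes were Mnx1; up to 4 detected members of each list with the largest difference between GFP high and GFP negative cells; the 10 genes with the largest and the 10 with the smallest difference in each comparison among genes detected on both arrays; and the 5 genes per comparison and direction with the largest lower bound. The position of GFP low cells was summarised as the number of genes ordered negative, low, high or the reverse, where chance gives each order 1 in 6.

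The steps were tested on simulated data for GFP high against GFP negative, with 9658 genes in the step and a noise SD of 0.25 on the log2 scale. Of 25 genes raised 3-fold, 92.0% were counted as at least 2-fold higher, and of 25 genes lowered 3-fold, 64.0% were counted as lower. All 25 genes raised 4-fold, all 25 raised 8-fold and all 25 lowered 4-fold were counted, as were 23 of 24 genes lowered 8-fold. The altered genes were drawn from those detected on all 3 arrays and were fewer than the genes counted in the data. Recovery of genes not detected on the dimmer array was therefore not tested. Of 9459 unaltered genes, 48 were counted, and 8.0% of 200 random lists lay outside the central 95% of their matched lists. The alternatives covered the background correction, the normalization between arrays, the authors' value table, the offset, the filter on dim probes, the treatment of several probes per gene and the size threshold.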

Results

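The 3 populations sorted from the differentiated cultures were compared by their reporter level: GFP high cells, which the labels call motor neurons, GFP low cells and GFP negative cells. There was 1 array per population and no replicate. The arrays were alike in overall brightness. The median non-normalized signal was 105.3 on the GFP high, 109.9 on the GFP low and 108.1 on the GFP negative array, and 11736, 11727 and 11689 probes were detected. Of 16593 genes, 8751 were detected on at least 1 array and 7464 on all 3. Across the 12808 probes detected on at least 1 array, which are not independent replicates, Pearson's r of the log2 signals was 0.934 between GFP high and negative, 0.976 between GFP high and low and 0.971 between GFP low and negative.

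Mnx1, the gene whose reporter was sorted on, had a log2 signal of 7.99 in GFP high, 5.30 in GFP low and 5.16 in GFP negative cells. Its signal was 7.09-fold higher in GFP high than in GFP negative cells and 6.44-fold higher than in GFP low cells. GFP low and GFP negative cells differed by 1.10-fold, a log2 difference of 0.14 that lies within the between-probe SD of 0.29. Mnx1 was measured by 1 probe, which was detected on all 3 arrays. Its GFP low and GFP negative signals lay close to the lowest signal of any detected probe, 5.13 and 5.14. The offset draws folds toward 1 there, so this probe cannot tell whether the 2 populations differ, and its folds for GFP high cells are understated.

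The comparison of GFP high with GFP negative cells asks what sets the cells with the brightest motor neuron reporter apart from cells of the same cultures without it. Genes of motor neuron identity and cholinergic transmission stood far higher in GFP high cells. Chat, which makes acetylcholine, was 50.2-fold higher by its brightest probe, with a dimmer second probe at a log2 difference of 4.29 against 5.65. Slc18a3, the vesicular acetylcholine transporter, was 41.2-fold higher. Isl1, a LIM homeodomain factor of motor neurons, was 47.2-fold higher. In the other direction, cell cycle genes such as Birc5 and Cdk1 were lower in GFP high cells by 7.02-fold and 5.43-fold, and the basement membrane collagen gene Col4a1 was lower by 33.0-fold.

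Of 8 detected motor neuron transcription factors, 6 were at least 2-fold higher in GFP high than in GFP negative cells, 5 with undetected genes at their bound, and 0 lower, with a median log2 difference of 1.94. Besides Isl1 and Mnx1 these included the LIM factors Lhx4, 7.40-fold higher, and Lhx3, 3.96-fold higher. Of 8 detected cholinergic and effector genes, 6 were at least 2-fold higher and 0 lower, with a median of 1.82, or 1.68 with undetected genes at their bound. This median was 0.78 without the normexp step, 1.02 when undetected genes were kept in and 2.57 in the authors' value table. Slit2, an axon guidance ligand, was 14.2-fold higher and Nrg1, a ligand of ErbB receptors, 4.68-fold higher. The probes for Slc5a7, the choline transporter, and Ache, acetylcholinesterase, were not detected on any array. No cranial motor neuron gene was detected in either population. Both motor neuron lists had medians above all 10000 random lists.

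General neuronal genes were also higher in GFP high cells. Of 18 detected pan-neuronal genes, 16 were at least 2-fold higher, 15 with bounds, and 0 lower, with a median of 1.71. The neurofilament gene Nefm was 9.98-fold higher, the stathmin family members Stmn4 and Stmn2 were 6.55-fold and 6.48-fold higher, and the growth cone gene Gap43 was 4.73-fold higher. Among synaptic vesicle and release genes, 10 of 14 were at least 2-fold higher and 0 lower, with a median of 1.46. The granin family genes Scg2, Chgb and Scg3 were higher by 4.16-fold, 3.71-fold and 3.41-fold, and Syt1, a calcium sensor of vesicle release, by 3.20-fold. Axon guidance and adhesion genes had a median of 0.83, or 0.49 with undetected genes at their bound, with 4 of 9 at least 2-fold higher, 3 with bounds, and 0 lower. Chl1 was at least 5.86-fold higher, the semaphorin receptor Nrp1 2.75-fold and the Slit receptor Robo1 2.33-fold. The axon guidance median was 0.29 without the normexp step and 0.29 with a detection p-value under 0.05. Of 4 detected voltage-gated channel genes, 3 were at least 2-fold higher, 2 with bounds, and 0 lower, with a median of 1.18, or 1.07 with bounds, led by the calcium channel subunit Cacna2d1 at 7.73-fold. The single probes for the neuronal genes Tubb3, Nefl and Snap25 were not detected on any array.

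Genes of dividing and progenitor cells were lower in GFP high cells. All 14 detected cell cycle genes were at least 2-fold lower, with a median log2 difference of -1.98, below all 10000 random lists. The replication licensing gene Mcm3 was 4.96-fold lower and the topoisomerase gene Top2a 4.95-fold lower. Of 14 detected neural progenitor genes, 6 were at least 2-fold lower, 5 with bounds, and 0 higher, with a median of -0.73, or -0.65 with bounds. Hes5 and Hes1, effectors of Notch signalling, were lower by 8.32-fold and 5.65-fold, Sox9 by 3.57-fold and the intermediate filament gene Nes by 2.60-fold, although another detected probe of Nes gave a log2 difference of -0.41. The progenitor factors Olig2 and Olig1 did not share this direction and were 1.41-fold and 1.51-fold higher in GFP high cells. Notch pathway genes had a median of -0.72, or -0.43 with bounds, with 4 of 12 at least 2-fold lower and 1 higher. Hes5 and Hes1 belong to both the progenitor and the Notch lists, which are therefore not independent. The receptors Notch3 and Notch1 were 4.85-fold and 2.59-fold lower, and the ligand Dll3 was 2.53-fold higher. Sonic hedgehog pathway and floor plate genes had a median of -0.92, or -0.91 with bounds, with 2 of 5 at least 2-fold lower, 1 with bounds, and 0 higher. Hhip, a Hedgehog-binding inhibitor, was at least 3.34-fold lower, and the ventral progenitor factor Nkx2-2 at least 1.88-fold lower.

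**Figure D1:**
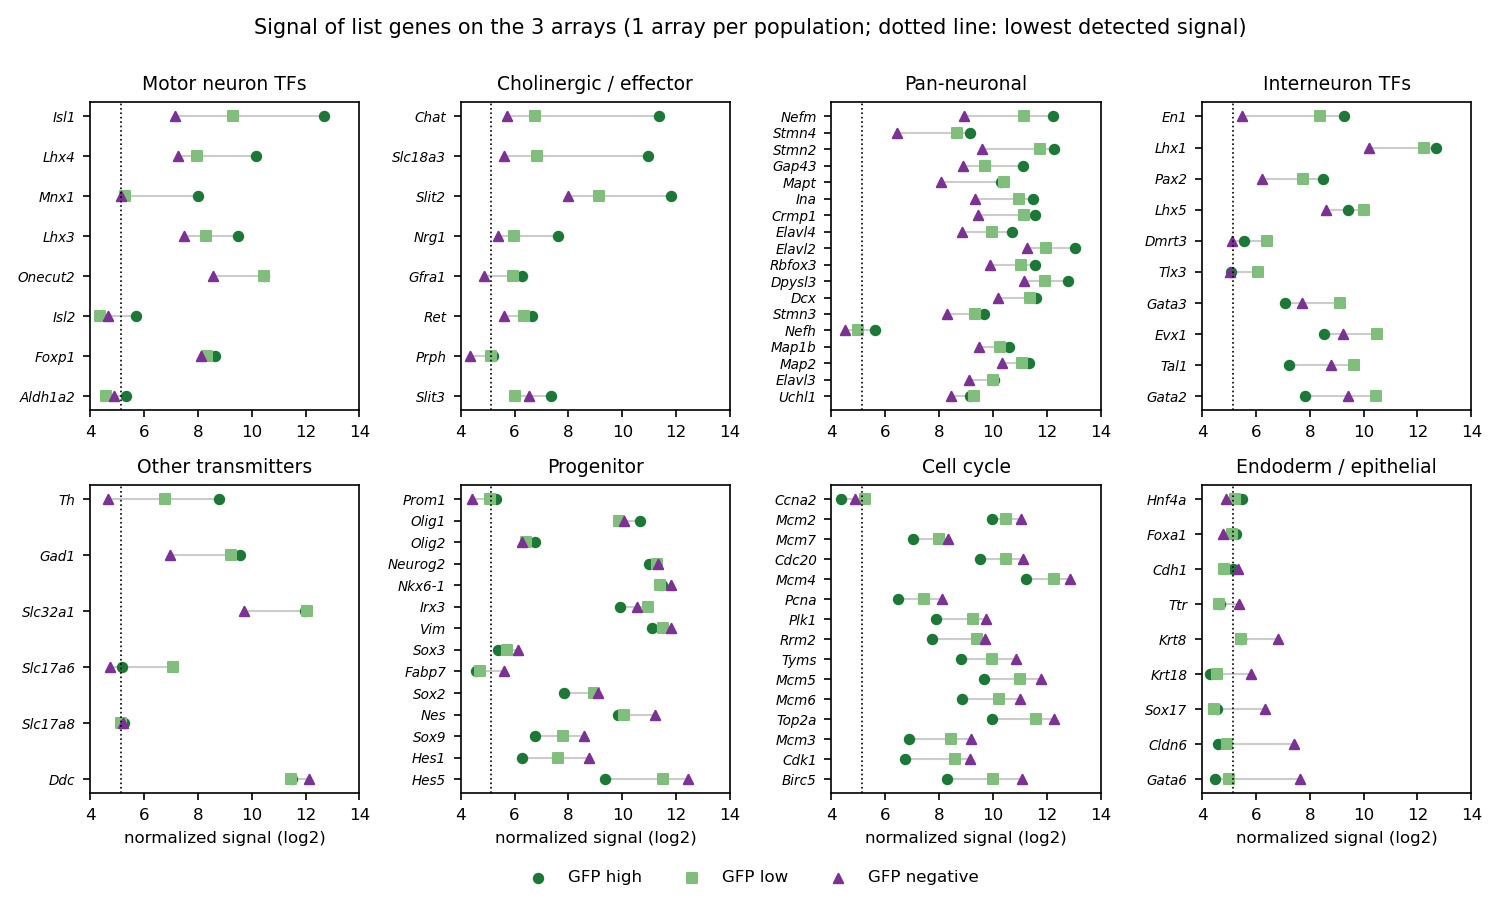
Normalized log2 signal (horizontal axis) of the members of 8 gene lists detected on at least 1 array, with 1 row per gene and 1 point per array for GFP high, GFP low and GFP negative cells. The dotted line marks the lowest signal of a detected probe, near 5.13, and Chat, Slc18a3 and Isl1 lie far to the right on the GFP high array while cell cycle genes lie to the left on it.

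Markers of other cell types did not move as 1 group. Spinal interneuron transcription factors split, with 3 of 9 at least 2-fold higher in GFP high cells, 2 lower and a median of 0.46, or 0.42 with bounds. En1, a marker of V1 interneurons, was 13.9-fold higher, Lhx1 5.64-fold and Pax2 4.81-fold, while Gata2, a factor of V2b interneurons, was 3.01-fold lower. Of 6 detected genes of other neurotransmitters, 3 were at least 2-fold higher and 0 lower, with a median of 1.36, or 1.16 with bounds and 0.20 when undetected genes were kept in. Th, which makes the catecholamine precursor L-DOPA, was at least 12.4-fold higher. Gad1, which makes GABA, was 6.17-fold higher, and Slc32a1, the vesicular transporter of GABA and glycine, was 4.81-fold higher. Of 4 detected glial genes, 2 were at least 2-fold lower and 1 higher, with a median of -1.14, or -0.73 with bounds. The glutamate transporter gene Slc1a3, also expressed in radial glia, was 9.45-fold lower and Pdgfra at least 3.15-fold lower. Mbp was 2.71-fold higher by its brightest probe and had a log2 difference of -0.07 by its other detected probe. The glial median was 0.20 over genes detected on both arrays, where Pdgfra, not detected in GFP high cells, is left out.

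Of 15 fibroblast, feeder and mesenchyme genes with a probe, 5 were detected, with a median of -2.22 and 4 of 5 at least 2-fold lower in GFP high cells and 0 higher. The median was -1.13 with the mean of a gene's probes and -0.038 when undetected genes were kept in. Sparc was 26.0-fold lower, Col5a1 7.71-fold lower and Fbln1 4.66-fold lower, the last with another detected probe at a log2 difference of -0.89. Acta2 was at least 2.14-fold lower, and its 3 detected probes ranged from -1.50 to -0.37. Of 9 detected endoderm and epithelial genes, 5 were at least 2-fold lower, 4 with bounds, and 0 higher, with a median of -1.36, or -0.70 with undetected genes at their bound. The endoderm factors Gata6 and Sox17 were at least 5.74-fold and 2.34-fold lower, and the tight junction gene Cldn6 at least 4.86-fold lower. Both detected endothelial genes, Esam and Flt1, were lower, by at least 2.02-fold and at least 1.63-fold, with a list median of -1.30, or -0.86 with bounds.

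Hox genes, which mark position along the body axis, differed little. Anterior Hox genes had a median of -0.04, with 0 of 11 members at least 2-fold higher or lower. Hoxb5 was 1.48-fold higher and Hoxd3 1.49-fold lower in GFP high cells. Posterior Hox genes had a median of 0.35, or 0.19 with bounds, with 1 of 11 at least 2-fold higher and 0 lower, and the higher gene was Hoxc6 at 2.50-fold. The posterior Hox median was -0.026 when undetected genes were kept in. Of 9 retinoic acid response genes, 1 was at least 2-fold higher and 1 lower, with a median of 0.04. The retinoid-binding gene Crabp1 was 2.33-fold higher and Cyp26a1, which degrades retinoic acid, 2.52-fold lower.

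Of 8 detected pluripotency genes, 1 was at least 2-fold higher and 1 lower, with a median of -0.21, or -0.17 with bounds, and a mean of 0.03, which differs in sign. Esrrb was 3.38-fold higher and Klf4 at least 2.14-fold lower, with another detected probe of Klf4 at a log2 difference of -0.66. Immediate early and stress genes had a median of 0.63, at percentile 99.93, with 3 of 12 at least 2-fold higher and 0 lower: Junb by 2.28-fold, Dusp1 by 2.20-fold and Fos by 2.02-fold. Of 12 motor neuron disease genes, 2 were at least 2-fold higher and 1 lower, with a median of 0.11. The kinesin gene Kif5a was 3.18-fold higher, with another detected probe at a log2 difference of 0.77, the autophagy receptor gene Sqstm1 was 2.05-fold higher, and the superoxide dismutase gene Sod1 was 2.33-fold lower. Glycolysis genes had a median of -0.21, with Eno2, the neuronal enolase, 3.44-fold higher and the hexokinase gene Hk2 2.61-fold lower. Reference genes had a median of -0.13 and a mean of 0.04. Among them B2m was 2.15-fold lower, and Actb was 1.99-fold higher with 5 detected probes from 0.03 to 1.33.

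Over all genes, 602 of 8613 were at least 2-fold higher and 851 at least 2-fold lower in GFP high than in GFP negative cells. Of these, 126 and 199 were not detected on the dimmer array, and with such genes at their bound the counts were 526 and 745. The highest genes detected on both arrays were Slc10a4, a transporter found in synaptic vesicles, at 57.7-fold, then Chat, Isl1, Slc18a3, the Slc10a4 relative Slc10a4l at 30.0-fold, Slit2, En1, Nefm, Marchf4 at 8.24-fold and Pax8 at 8.15-fold. The probes of Slc10a4 disagreed in size, with a dimmer second probe at a log2 difference of 2.37 against 5.85, and those of Pax8 gave 1.35 and 3.03. Slc10a4 and Slc10a4l are close in name and may share hybridisation, so their separate values are uncertain. Genes not detected in GFP negative cells were led by Rasgef1c, at least 15.2-fold higher with a second probe at a log2 difference of 2.85, Th, Ecel1 at least 10.7-fold, the glycine receptor gene Glra2 at least 9.32-fold and Cldn3 at least 7.87-fold. The lowest genes after Col4a1 and Sparc were the replication-dependent histone genes H2ac11 at 15.8-fold, H2ac21 at 13.8-fold, H2ac12 at 11.9-fold, H2ac7 at 9.70-fold and H2ac15 at 9.48-fold, near-identical copies whose probes cannot be taken as separate. Kif15, a mitotic kinesin, was 10.6-fold lower, the ligand gene Wnt7a 9.48-fold lower and Slc1a3 9.45-fold lower. Genes not detected in GFP high cells were led by Col4a2, at least 26.2-fold lower, the embryonic globin gene Hbb-y at least 14.8-fold, Dab2 at least 12.6-fold, the globin gene Hba-x at least 9.91-fold and Yap1 at least 9.53-fold. The globin genes belong to 1 gene family, and whether their probes share hybridisation was not checked. In the 374 genes whose brightest of 2 or more detected probes differed at least 2-fold, the second probe had the same sign in 358, and in 0 was it at least 2-fold the other way. The counts were 229 and 406 without the normexp step and 356 and 567 with an offset of 50.

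**Figure D2:**
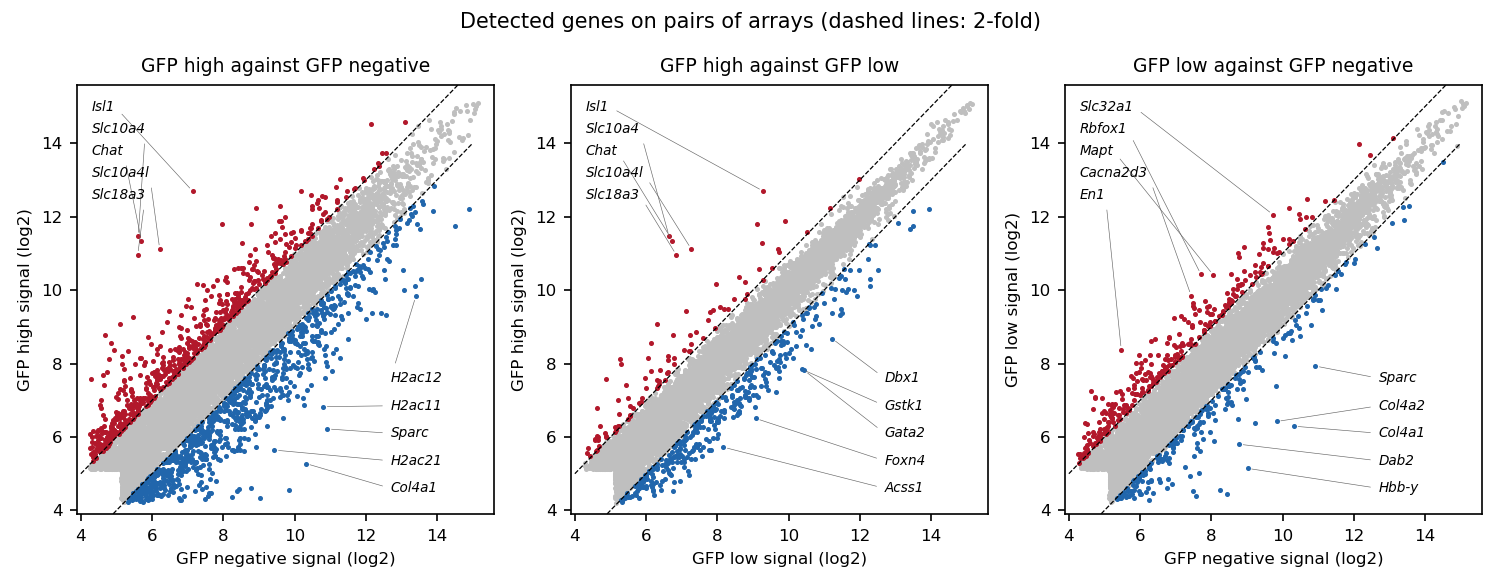
Normalized log2 signal of genes detected on at least 1 of the 2 arrays in each comparison, with 1 point per gene and dashed lines at 2-fold. Red points are at least 2-fold higher and blue points at least 2-fold lower on the array of the vertical axis, 602 and 851 genes for GFP high against negative, 93 and 351 for GFP high against low and 287 and 228 for GFP low against negative, with the 5 genes of largest difference detected on both arrays named per direction.

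The comparison of GFP high with GFP low cells asks what separates cells by the strength of the reporter. Motor neuron genes were again among the highest. Chat was 24.5-fold higher in GFP high than in GFP low cells by its brightest probe, a log2 difference of 4.61 with a dimmer second probe at 3.66, Slc18a3 17.3-fold and Isl1 10.6-fold. In the other direction the lowest genes detected on both arrays were Gata2 at 6.20-fold, the V2 progenitor factor Foxn4 at 5.97-fold and the V0 progenitor factor Dbx1 at 5.84-fold.

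Of 8 detected motor neuron transcription factors, 5 were at least 2-fold higher in GFP high than in GFP low cells, 4 with bounds, and 0 lower, with a median log2 difference of 1.25, or 0.87 with undetected genes at their bound. Lhx4 was 4.61-fold higher and Lhx3 2.27-fold higher, while Onecut2 differed by 1.01-fold. Cholinergic and effector genes had a median of 1.49, with 5 of 8 at least 2-fold higher and 0 lower, among them Slit2 at 6.37-fold and Nrg1 at 3.10-fold. General neuronal genes differed less. Pan-neuronal genes had a median of 0.48, or 0.47 with bounds, with 3 of 18 at least 2-fold higher and 0 lower: Gap43 by 2.69-fold, Nefm by 2.08-fold and Elavl2 by 2.07-fold. Synaptic genes had a median of 0.22, with 0 of 14 at least 2-fold higher or lower. Axon guidance genes had a median of 0.21, with Nrp1 2.98-fold higher, and channel genes a median of 0.58, with Cacna2d1 4.95-fold higher.

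Cell cycle genes were lower in GFP high than in GFP low cells, with 10 of 15 at least 2-fold lower, 0 higher and a median of -1.35. Cdk1 was 3.70-fold and Birc5 3.33-fold lower. Neural progenitor genes had a median of -0.35, with 5 of 13 at least 2-fold lower and 0 higher, Notch pathway genes a median of -0.46 with 3 of 11 lower and 0 higher, and Sonic hedgehog genes a median of -0.55, or -0.49 with bounds, with 1 of 5 lower, 0 with bounds, and 0 higher. Hes5 and Hes1, members of both the progenitor and the Notch lists, were 4.39-fold and 2.49-fold lower. Of 10 detected interneuron transcription factors, 5 were at least 2-fold lower in GFP high cells, 4 with bounds, and 0 higher, with a median of -0.93, below all random lists, or -0.91 with bounds. After Gata2 these were Tal1 at 5.37-fold, Gata3 at 4.13-fold, Evx1 at 3.91-fold and Tlx3, whose bound of at least 1.95-fold lies under 2-fold. En1 went the other way and was 1.86-fold higher in GFP high cells. Other neurotransmitter genes had a median of 0.07, with Th 4.03-fold higher and Slc17a6, the vesicular glutamate transporter, 3.65-fold lower.

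Among the remaining lists, fibroblast genes had a median of -1.25 over 3 detected members, all at least 2-fold lower in GFP high cells, with Sparc at 3.28-fold. The fibroblast median was 0.037 when undetected genes were kept in. Endoderm genes had a median of 0.20, or 0.08 with bounds, glial genes of -0.20 and pluripotency genes of 0.13, or 0.08 with bounds. The endothelial gene Esam was at least 1.40-fold lower in GFP high cells and the cranial motor neuron gene Phox2a at least 1.14-fold lower, each the single detected member of its list, with medians of -0.64 and -0.73, or -0.48 and -0.19 with bounds. Anterior and posterior Hox genes had medians of -0.32 and -0.30, with 0 members of either list at least 2-fold higher or lower. Immediate early and stress genes had a median of 0.25, motor neuron disease genes of 0.13, retinoic acid response genes of -0.08, glycolysis genes of -0.04 and reference genes of -0.05.

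Over all genes, 93 of 8427 were at least 2-fold higher and 351 at least 2-fold lower in GFP high than in GFP low cells, or 79 and 308 with undetected genes at their bound. In the authors' value table the counts were 300 and 597, so that 33.4% of the genes counted were higher there against 20.9% in the main setting. The counts were 34 and 127 without the normexp step and 49 and 199 with an offset of 50. Slc10a4 was 28.1-fold higher, Slc10a4l 14.4-fold, Cldn3 7.26-fold, Rasgef1c 6.77-fold and Ecel1 5.32-fold. Dimmer second probes gave smaller log2 differences, 2.27 against 4.81 for Slc10a4 and 1.92 against 2.76 for Rasgef1c. Genes not detected in GFP low cells were led by the neuropeptide gene Uts2b, at least 5.50-fold higher, Nfe2 at least 3.17-fold, Vwa2 at least 2.25-fold, Mcoln3 at least 2.20-fold and Pvr at least 2.02-fold. Among the lowest genes, Gstk1 was 5.76-fold and Acss1, a mitochondrial acetyl-CoA synthetase, 5.45-fold lower. The replication checkpoint gene Clspn was 4.70-fold lower by its brightest probe, with 4 detected probes down to a log2 difference of -0.61. The histone genes H2ac11, H2ac7 and H2ac21 were 4.70-fold, 4.52-fold and 4.49-fold lower, again as close copies. Genes not detected in GFP high cells were led by Tfap2c, at least 4.20-fold lower with a second probe at a log2 difference of -1.16, Nrn1 at least 4.13-fold, Fam167a at least 3.54-fold, Elfn1 at least 3.13-fold and Yap1 at least 3.09-fold. The second probe had the sign of the brightest in 110 of 116 genes.

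The comparison of GFP low with GFP negative cells asks what marks weak reporter activity. Neuronal and interneuron genes were higher in GFP low cells. En1 was 7.47-fold higher, Slc32a1 5.01-fold, the microtubule gene Mapt 5.14-fold and Gad1 4.91-fold. In the other direction Col4a1 was 16.3-fold, the globin gene Hbb-y 14.7-fold and Sparc 7.94-fold lower.

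Of 10 detected interneuron transcription factors, 9 were at least 2-fold higher in GFP low than in GFP negative cells, 8 with undetected genes at their bound, and 0 lower, with a median log2 difference of 1.36, above all random lists, or 1.34 with bounds. Lhx1 was 4.13-fold, Pax2 2.93-fold, Gata3 2.71-fold and Lhx5 2.66-fold higher. Other neurotransmitter genes had a median of 2.19, or 1.77 with bounds, with 4 of 6 at least 2-fold higher and 0 lower. Slc17a6 was at least 3.79-fold and Th at least 3.09-fold higher. Pan-neuronal genes had a median of 1.09 with 10 of 17 at least 2-fold higher, and synaptic genes a median of 1.06 with 7 of 14 higher, in both lists with 0 lower. Stmn4 was 4.77-fold, Stmn2 4.42-fold, Scg2 3.66-fold and Syt1 3.48-fold higher. The motor neuron transcription factor list had a median of 0.74, with 2 of 6 at least 2-fold higher and 0 lower, and the cholinergic list a median of 1.04, or 0.80 with bounds, with 4 of 7 higher, 3 with bounds, and 0 lower. Isl1 was 4.44-fold, Slc18a3 2.38-fold and Chat 2.05-fold higher. Axon guidance genes had a median of 0.28 and channel genes of 0.62, or 0.17 and 0.49 with bounds.

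Cell cycle genes were modestly lower in GFP low than in GFP negative cells, with a median of -0.63, below all random lists, and 1 of 15, Birc5 at 2.11-fold, at least 2-fold lower. Neural progenitor genes had a median of -0.39 with 2 of 13 at least 2-fold lower, Notch pathway genes of -0.44, or -0.26 with bounds, with 2 of 12 lower and Sonic hedgehog genes of -0.54 with 0 of 5 lower. None of these 3 lists had a member at least 2-fold higher. Endoderm and epithelial genes had a median of -1.32, or -0.96 with bounds, with 5 of 8 at least 2-fold lower, 4 with bounds, and 0 higher, Gata6 by at least 5.73-fold and Cldn6 by at least 4.85-fold. Fibroblast genes had a median of -1.60, or -1.10 with bounds, with 3 of 5 lower and 0 higher, and endothelial genes a median of -1.01, or -0.62 with bounds, over 2 detected genes. Glial genes had a median of -0.60, which was 0.12 among genes detected on both arrays. Posterior Hox genes had a median of 0.48, or 0.40 with bounds, with Hoxc6 2.51-fold higher, and anterior Hox genes of 0.17 with Hoxb1 2.31-fold higher. Medians were -0.18 for pluripotency genes, 0.13 for retinoic acid response genes, 0.16 for immediate early and stress genes, 0.13 for motor neuron disease genes (0.03 with bounds), -0.10 for glycolysis genes and 0.08 for reference genes. The cranial motor neuron gene Phox2a was at least 1.13-fold higher, with a list median of 0.41, or 0.18 with bounds.

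Over all genes, 287 of 8516 were at least 2-fold higher and 228 at least 2-fold lower in GFP low than in GFP negative cells, or 249 and 187 with undetected genes at their bound. The splicing factor gene Rbfox1 was 6.59-fold higher, the calcium channel subunit Cacna2d3 5.33-fold, the growth factor gene Ptn 4.98-fold, the calcium-binding gene Calb2 4.79-fold, with a second probe at a log2 difference of 1.36, and Nefm 4.79-fold. Genes not detected in GFP negative cells were led by Chl1, at least 4.29-fold higher, Diras2 at least 3.87-fold, Glra2 at least 3.80-fold, Slc17a6, and the cortactin gene Cttn at least 3.37-fold, although another of the 4 detected probes of Cttn gave a log2 difference of 0.03. The lowest genes also held Col4a2 at 10.7-fold, the endocytic adaptor Dab2 at 7.88-fold, Hs3st1 at 7.15-fold, Erich5 at 5.39-fold, Prf1 at 4.86-fold, Rhox5 at 4.57-fold and S100a1 at 4.21-fold. Genes not detected in GFP low cells were led by the globin genes Hba-x, at least 9.89-fold lower, and Hba-a1, at least 8.72-fold, then Gata6, Hbb-bh1 at least 5.45-fold and Pga5 at least 5.12-fold. The authors' value table gave counts of 510 and 542, against 92 and 69 without the normexp step and 165 and 107 with an offset of 50. The second probe had the sign of the brightest in 102 of 106 genes.

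**Figure D3:**
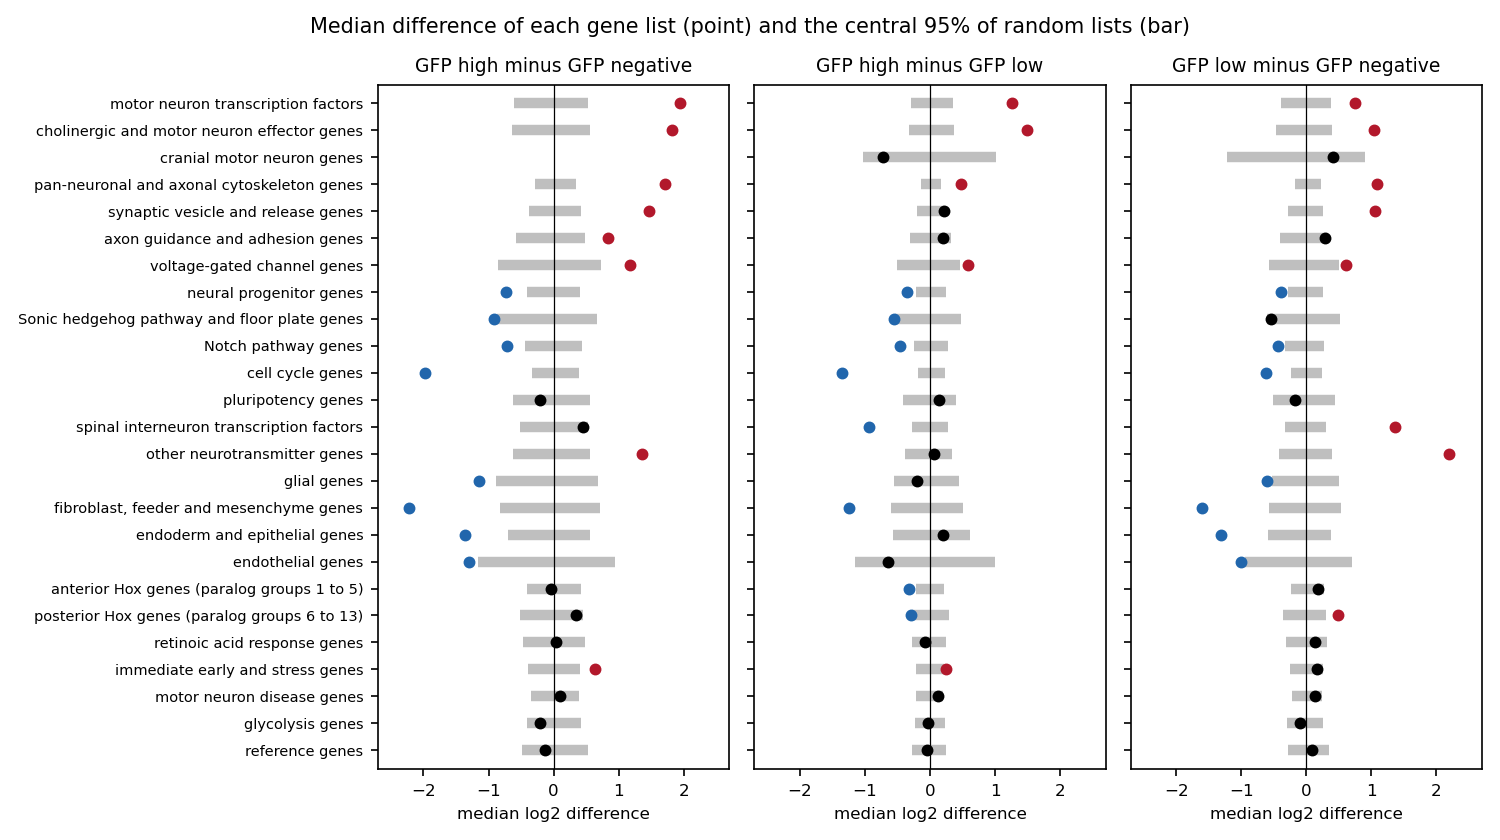
Median log2 difference of each gene list over its detected members (point) in the 3 comparisons, with the central 95% of 10000 random lists of the same size and signal as a grey bar. Points outside the bar are red when higher and blue when lower, such as cell cycle genes at -1.98, -1.35 and -0.63 from left to right, and cranial motor neuron genes have no point in the left panel because none was detected.

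GFP low cells lay between the other populations for many list genes. Of 226 detected list genes, 85 were ordered negative, low, high and 60 the reverse, where chance gives 37.7 for each order. These shares, 37.6% and 26.5%, compare with 30.1% and 29.0% over all detected genes, so the reverse order was no commoner among list genes. Pan-neuronal genes followed the first order in 16 of 18, synaptic genes in 11 of 14, cholinergic genes in 7 of 8 and motor neuron transcription factors in 6 of 8, while cell cycle genes followed the reverse in 14 of 15. Interneuron transcription factors did not, with 7 of 10 in neither order. Over all 8751 detected genes the counts were 2637 and 2542, where chance gives 1458.5. Among the 1453 genes at least 2-fold different between GFP high and negative cells, 544 and 811 were in order, a share raised by choosing genes on the 2 outer populations.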

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

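All alternatives were planned. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. The 3 changes to the filter on dim probes cannot alter the difference of a single gene. Under the other 5 alternatives none of the 174 values of named genes changed sign, but many changed in size by more than the between-probe SD: 122 without normexp, 93 with an offset of 50, 74 in the authors' value table, 35 with the mean of a gene's probes and 0 with equal medians in place of quantile normalization. Values of at least 2-fold came to between 0.23 and 1.78 times their log2 difference. Equal medians moved each of 74 list medians by less than the between-probe SD and each count by less than 1.5 times, but shifted the balance of genes: 36.4% of those at least 2-fold different were higher in GFP high than negative cells against 41.4%, 15.8% against 20.9% for GFP high against low and 60.2% against 55.7% for GFP low against negative. Among list medians under 2-fold, 10 of 405 alternative values had the other sign, and among those of at least 2-fold, 2 of 183. The median over all genes moved by less than 0.1 under each scaling. Signal over background limits dim genes most: settings that leave more background in the signal draw their folds toward 1, as their construction implies. Elsewhere the cause was not tested.

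For the counts at least 2-fold higher and lower in GFP high against negative (602 and 851), GFP high against low (93 and 351) and GFP low against negative (287 and 228), quantile normalization without normexp gave 229 and 406, 34 and 127, and 92 and 69. Equal medians gave 518 and 904, 75 and 401, and 314 and 208. An offset of 50 gave 356 and 567, 49 and 199, and 165 and 107. The 1.5-fold threshold gave 1558 and 1703, 543 and 827, and 879 and 996, more by construction. The authors' value table gave 903 and 1187, 300 and 597, and 510 and 542.

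The list medians given are those that moved by at least the between-probe SD for GFP high minus negative, unless stated. Of the 50 medians of the other 2 comparisons, 18 changed as much without normexp, 10 with an offset of 50, 10 in the authors' value table, 4 with a detection p-value under 0.05, 18 with no detection filter and 2 with the mean of a gene's probes, as did 5 of 47 over genes detected on both arrays. Without normexp the medians were 1.49 for motor neuron transcription factors, 0.78 for cholinergic and effector genes, 1.02 for synaptic, 0.29 for axon guidance, 0.62 for channel, -0.43 for Sonic hedgehog, -1.63 for cell cycle, -0.41 for glial, -1.63 for fibroblast, -0.50 for endoderm and -0.42 for endothelial genes. With an offset of 50 they were 1.21 for cholinergic, 0.49 for axon guidance, 0.82 for channel, -0.63 for glial, -0.75 for endoderm and -0.70 for endothelial genes. In the authors' value table they were 2.57 for cholinergic, 1.23 for axon guidance, 1.81 for channel, -1.06 for Notch, 0.79 for interneuron, -1.52 for glial, -2.62 for fibroblast, -1.78 for endoderm and -1.98 for endothelial genes.

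Over genes detected on both arrays the medians were 2.41 for motor neuron transcription factors, 3.02 for cholinergic, -0.48 for Sonic hedgehog, 0.10 for interneuron, -2.95 for fibroblast and -0.78 for endoderm genes. The glial median reversed there to 0.20, from -1.14, and for GFP low minus negative to 0.12, from -0.60. With a detection p-value under 0.05 the medians were 0.29 for axon guidance and -1.86 for fibroblast genes, and the glial median for GFP low minus negative reversed to 0.12. With no detection filter they were 1.02 for cholinergic, 0.22 for axon guidance, 0.69 for channel, -0.44 for Sonic hedgehog, 0.20 for other neurotransmitter, -0.014 for glial, -0.038 for fibroblast, -0.61 for endoderm, -0.19 for endothelial and -0.026 for posterior Hox genes. There the fibroblast median for GFP high minus low reversed to 0.037, from -1.25, and the glial median for GFP low minus negative to 0.10. With the mean of a gene's probes they were 0.40 for axon guidance, -0.48 for Sonic hedgehog, -1.63 for cell cycle, -1.13 for fibroblast and -0.94 for endothelial genes.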

Other observations

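The gene lists used in this part beyond those of the report were drawn up after the values of some members had been seen. The tests on a motor neuron gap, on interneuron factors in GFP low cells, on V1-type genes and on feeder fibroblasts were chosen only after the result was seen.

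Clustered histone genes were lower in GFP high cells as a family. Of 45 with a probe, 38 were detected, and 29 of these were at least 2-fold lower in GFP high than in GFP negative cells and 0 higher. The median log2 difference was -2.05, and -1.12 without normexp, with -0.72 for GFP high minus low and -1.10 for GFP low minus negative. The set spans several histone classes, and genes within 1 class are close copies, so its members cannot be taken as separate measurements.

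Some genes were brightest in GFP low cells. In 19 of 8751 detected genes the GFP low signal was at least 2-fold above both other populations, against 73 for GFP high and 196 for GFP negative cells. They included Slc17a6, 3.65-fold above the brighter of the others, the growth factor gene Ptn at 3.22-fold, Nrn1 at 3.21-fold, the V2b factor Gata3 at 2.71-fold, Msx1 at 2.51-fold, the V0 factor Evx1 at 2.37-fold and the dorsal factor Olig3 at 2.32-fold. These were picked after their values were seen, and how many of the 19 exceed noise was not tested. For scale, 48 of 9459 unaltered genes in the simulation were counted as at least 2-fold different between 2 arrays, a looser criterion. Of 6 detected V0 and V2b-type interneuron genes, with a median of -2.01 for GFP high minus low, 4 had been seen before; the other 2, Vsx1 and Lmo4, had a median of -0.91 and were brightest in GFP negative cells, with -0.41 for GFP low minus negative. Of 5 detected dorsoventral progenitor domain factors, with medians of -1.59 for GFP high minus low and -0.18 for GFP low minus negative, the 3 not looked at when the list was drawn up, Msx1, Irx5 and Sp8, had medians of -0.83 and 0.18.

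GFP low cells could be a mixture of GFP high and GFP negative cells, which would place every gene at about the same share of the way between the 2 signals on the linear scale. Shares were taken over genes at least 2-fold different between GFP high and GFP negative cells. The planned test pooled the motor neuron lists with the pan-neuronal and synaptic lists as neuronal lists. It did not argue against a mixture: neuronal lists had a median share of 0.59 and progenitor and cell cycle lists of 0.54, a difference of 0.0524, and their interquartile ranges overlapped. A later test, which split that pool, did argue against a mixture. Motor neuron genes lay at a median share of 0.09 (interquartile range 0.03 to 0.35, 12 genes) and pan-neuronal and synaptic genes at 0.63 (0.50 to 0.76, 26 genes), a difference of -0.536. Interneuron factors were also brighter in GFP low cells than in both others by a median log2 gap of 0.861 over 10 genes. Of these, 7 were above both and 4 at least 2-fold above both, which a mixture would not give. The 4 include Tlx3, which lies under 2-fold at its bound. The interquartile range of -0.19 to 1.04 includes 0, so that the gap of the list as a whole does not decide. The median gap was 0.44 without normexp, 0.58 with an offset of 50 and 0.95 in the authors' value table. A distinct, more interneuron-rich population in the GFP low gate stays open as a hypothesis, with 1 array and no independent test.

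En1, Pax2, Pax8, Slc32a1 and Gad1, the genes that prompted a list of V1-type interneuron genes, were at least 2-fold above GFP negative cells in GFP high cells. The only other detected member, Prdm8, was at a log2 difference of -0.46, and Foxd3, Foxp2, Otp and Calb1 were not detected. Slc32a1 and Gad1 were also on the list of other neurotransmitter genes, so the V1-type list is not particular to V1 cells. Carry-over of GFP low cells into the GFP high gate may be considered, and would bring V1-type and other interneuron genes at 1 share of their GFP low signal. On the linear scale the GFP high signal was a median of 1.48 times the GFP low signal over the 6 detected V1-type genes (interquartile range 1.04 to 1.85). Over 6 V0 and V2b-type genes it was 0.20 times (0.17 to 0.24), a difference of 1.28. Both lists were built around genes already seen, so this gap partly restates their choice. The members not seen before did not separate the lists, with Prdm8 at 0.73, Lmo4 at 0.90 and Vsx1 not detected in GFP high cells. Among the genes seen before, Gata2, Tal1, Gata3 and Evx1 stood at 0.15 to 0.25. En1, Pax2, Pax8, Slc32a1 and Gad1 stood at 0.96 to 2.32. For these genes 1 share cannot give both ranges. This argues against carry-over of GFP low cells as a whole as the only source of the En1, Pax2, Pax8, Slc32a1 and Gad1 signal. It does not exclude a smaller carry-over beside another source, or carry-over of a part of GFP low cells rich in these transcripts. Earlier forms of this test, on Prdm8 as the only detected member not looked at before and on the median log2 difference of 0.524 against the spread between probes, were set aside because 1 gene and technical spread decide nothing. Whether V1-type or other interneurons activate the reporter, or motor neurons carry these transcripts, was not tested.

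In GFP negative cells the globin genes Hba-x, Hbb-y, Hba-a1 and Hbb-bh1 had log2 signals of 8.43, 9.02, 8.25 and 7.57, and Col4a1, Col4a2 and Sparc of 10.32, 9.84 and 10.92. The cells that made these transcripts were not identified, and the lists below do not tell the candidate sources apart. Sparc was on both the primitive and parietal endoderm list and the fibroblast list. Lama1 and Lamc1 of the endoderm list were also bright in GFP high cells, at log2 signals of 8.94 and 8.19. Primitive or parietal endoderm cells in that gate are a candidate source that stays open: of 13 markers with a probe not looked at before, Lamb1, Plat, Thbd and Cited1 were not detected and Amn was in GFP high cells only, and the other 8 had a median log2 difference of 1.24 for GFP negative minus low, and 5 of them (Lama1, Lamc1, Fst, Srgn and Serpinh1) were at least 2-fold higher, the majority that the planned test asked for. With Srgn, which was not detected in GFP low cells, at its bound, a step decided after the result was seen, these were 4 of 8 and the median was 0.99, short of that majority, while without bounds there were 2 of 8 with a median of 0.51 without normexp, 3 of 8 with 0.78 with an offset of 50, 5 of 8 with 1.22 with equal medians and 8 of 8 with 1.44 in the authors' value table. Erythroid cells stay open as well: across all 6 detected members the median was 3.43, or 2.79 with bounds, but the 2 not looked at before, Car2 and Blvrb, had a median of 0.832 (0.49 without normexp), and the other 7 of 9 with a probe, Alas2, Klf1, Gata1, Slc4a1, Epor, Hemgn and Epb42, were not detected on any array. Feeder fibroblasts stay open too: all 5 detected members of the fibroblast list, Sparc, Col5a1, Fbln1, Acta2 and Twist1, were brighter in GFP negative than in GFP low cells, while 0 of 6 abundant fibroblast transcripts (Col1a1, Col1a2, Col3a1, Postn, Lum and Dcn) were detected in GFP negative cells by any of 8 probes, which were not detected on the other arrays either, so that probe failure cannot be told apart from absence.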
